A study of Homo sapiens with 9 samples.

How the data were processed

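Total RNA from transfected SAOS-2 cells was measured on 9 arrays, 3 each for scrambled siRNA, RBP2 siRNA and pRB. Per the labels, cells received 1 µg of plasmid and 40 nM siRNA, were selected with 0.6 µg/ml puromycin, and were transfected and harvested separately for each numbered set of 3 samples.

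The values used were the deposited table of probe set intensities, 1 intensity per probe set and array on a linear scale. How the authors summarised and normalised them is not given in the sources used here. Between 0.491% and 0.995% of values per array were below 0, so background had been subtracted, and the distributions of the arrays were not identical. Of 22277 probe sets, 62 control probe sets were left out and 22215 kept. Array medians lay within 0.168 of each other on the log2 scale, inside the limit of 0.2 set for using the arrays as deposited. Values under the 25th percentile of all values (51.18) were raised to it before taking log2. Probe sets were tested where their mean log2 value over all arrays was above the 40th percentile of these means (6.395), which left 13329 probe sets representing 7973 genes. Group means and SDs in the text are of the deposited intensities, before the floor.

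Probe sets were named from the supplied annotation. Of those kept, 19064 had 1 gene symbol, 1043 had several and 2108 had none, and 19052 symbols matched a RefSeq gene. Genes were named from probe sets with 1 symbol.

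Comparisons used linear models in limma 3.58.1 under R 4.3.3, fitted to all 9 arrays with 1 mean per group and moderated by eBayes with an intensity trend. Tests were two-sided, and Benjamini-Hochberg adjustment was over all tested probe sets, with a threshold of 0.05. This left 6 residual degrees of freedom, or 4 with the numbered set as a block. The numbered sets were checked as pairs by correlating, within each set, the deviations of its arrays from their group means. All 9 correlations were above 0, from 0.198 to 0.772, so blocked counts are given beside the others. RNA integrity was read from the ratio of 3' to 5' control probe sets for actin and GAPDH. Precision is limited by the number of arrays.

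Before the data were examined, the tests, most alternatives, the rule for naming genes and 30 gene lists were fixed. Lists were tested where at least 5 members were measured, with 1 probe set per gene (the brightest), by camera with its preset correlation of 0.01 and adjustment over the 29 lists tested, and again with an estimated correlation. The rotation test fry, which asks whether a list moves 1 way on balance without comparing it with other genes, was run beside it. With an estimated correlation, ribosome biogenesis for RBP2 siRNA against scrambled siRNA and mitosis for pRB against scrambled siRNA kept their calls, and no list did for RBP2 siRNA against pRB. With the numbered set as a block as well, these calls were lost (adjusted p = 0.151 and 0.145). The lists covered the cell cycle, differentiation, metabolism, translation, splicing, chromatin, stress and matrix genes, and markers of epithelial, blood, adipocyte, muscle, neuronal, chondrocyte and endothelial cells. The endothelial list had 4 measured genes and was not tested. Passing members were also counted with adjustment over the list alone.

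Genes named were KDM5A and RB1, then for each comparison the 10 largest rises and 10 largest falls among probe sets that passed and moved the same way in all 3 sets, up to 4 members of smallest p in each shifted list, and up to 5 genes per direction shared by the comparisons with scrambled siRNA. In every comparison all passing probe sets moved the same way in all 3 sets. A few genes outside this rule are named where 5 or fewer members of a list passed, and are said in the text to be chosen after their values were seen.

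The overlap of the comparisons with scrambled siRNA was set against the product of the separate counts divided by the number tested, and its correlation against 100 simulations of unchanged groups sharing 3 controls, with arrays drawn independently. Another 100, added after the results were seen, carried the correlations within numbered sets. The method was tested on simulated data with 100 changed probe sets of each of 2 sizes per comparison. At a 2-fold change it recovered 74%, 71% and 79% of them in the 3 comparisons, at a log2 change of 0.585 it recovered 26%, 26% and 16%. Of 105, 103 and 104 calls 5, 6 and 9 were false. With no changed probe sets it made 0 calls in limma. A list of 30 genes shifted by 0.3 was found by camera, and 0 of 29 random lists were. Genes and arrays were drawn independently in these tests, so they do not show how camera calls lists of correlated genes. The heat shock list, for example, had an estimated correlation of 0.61.

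Alternatives were quantile normalization, scaling to equal medians, a pseudocount of 16 in place of the floor, a floor at the 40th percentile, no filter, a filter at the 60th percentile, no intensity trend, robust moderation, array weights, only the 6 arrays compared, the numbered set as a block, 1 probe set per gene, an adjusted p under 0.10, a fold change of at least 1.5, and leaving out each array and each set. Further alternatives were chosen after the RNA integrity ratios were seen. They left out the treated arrays of set 2, with and without the block, or used the mean log2 ratio of actin and GAPDH as a covariate. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.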

Results

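Gene expression was measured in SAOS-2 cells, an osteosarcoma line without functional retinoblastoma protein (pRB), on 9 single-colour oligonucleotide arrays hybridised with biotin-labelled RNA copies. The arrays formed 3 groups of 3. Control cells received a scrambled siRNA and an empty plasmid. Cells labelled RBP2 siRNA received an siRNA against RBP2 (gene KDM5A, a histone H3 lysine demethylase that binds pRB) and the empty plasmid. Cells labelled pRB received a plasmid for residues 379 to 928 of pRB and the scrambled siRNA. Each of 3 numbered sets held 1 array of each group, from transfections and RNA isolations of its own. RNA was taken on day 5 in the scrambled and RBP2 siRNA cells and on day 3 in the pRB cells, so pRB and day cannot be told apart. Median intensities ran from 112.8 to 126.7. Between 23.9% and 26.8% of probe sets lay at the lower floor used for the comparisons, and the number of arrays limits the precision.

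RNA integrity differed between arrays. Each array carries probe sets near the 3' end and near the 5' end of the actin and GAPDH transcripts, and their ratio increases as RNA breaks down. The actin ratio was 1.05 to 1.18 in the 3 scrambled siRNA arrays, 5.03 in RBP2 siRNA set 2 and 1.70 in pRB set 2. The GAPDH ratio was 0.958 to 1.04 in the scrambled siRNA arrays, 2.18 in RBP2 siRNA set 2 and 1.22 in pRB set 2. RBP2 siRNA set 2 also had the lowest mean correlation across genes with the other arrays, 0.911. RBP2 siRNA set 3 lay slightly above every scrambled siRNA array too, at 1.21 for actin and 1.14 for GAPDH, with a mean correlation of 0.946. In every set both ratios were higher in the RBP2 siRNA array than in the scrambled siRNA array, so RNA integrity differed along with the group.

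**Figure D1:**
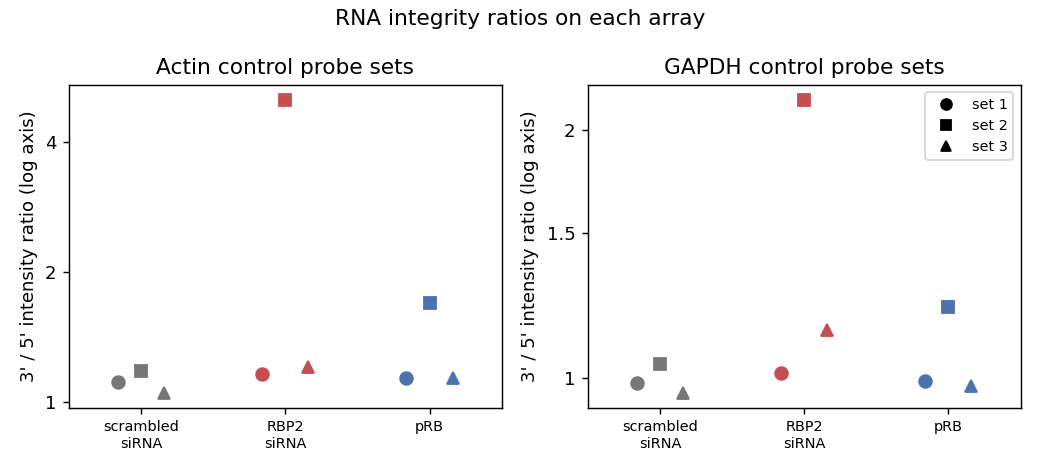
Ratio of 3' to 5' control probe set intensity for actin (left) and GAPDH (right), on log axes without units, with 1 symbol per array, colour for the group and shape for the numbered set (n = 3 per group). RBP2 siRNA set 2 lies highest in both panels, at 5.03 for actin and 2.18 for GAPDH.

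The siRNA target was not lower in the arrays labelled RBP2 siRNA. KDM5A, on chromosome 12, read 463 ± 31.2 in scrambled siRNA arrays, 590 ± 111 in RBP2 siRNA arrays and 577 ± 74.6 in pRB arrays (the brighter of its probe sets, SD, n = 3 each). The log2 difference of RBP2 siRNA from scrambled siRNA was 0.34 (SE 0.147, limma adjusted p = 0.226) and lay above 0 in all 3 sets, from 0.184 to 0.520. With the numbered set as a block its adjusted p was 0.0363. A dimmer KDM5A probe set gave 170 ± 34.7, 166 ± 6.66 and 174 ± 19.8. Of the probe sets for RB1, on chromosome 13, 1 lay at the floor on all 9 arrays and another gave 147 ± 15.5, 92.9 ± 61.7 and 130 ± 35.8, a log2 difference of pRB from scrambled siRNA of -0.22 (adjusted p = 0.885). Where these RB1 probe sets lie relative to the expressed fragment is not known here, so whether they detect the plasmid transcript is open. Groups are named by their labels in what follows.

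**Figure D2:**
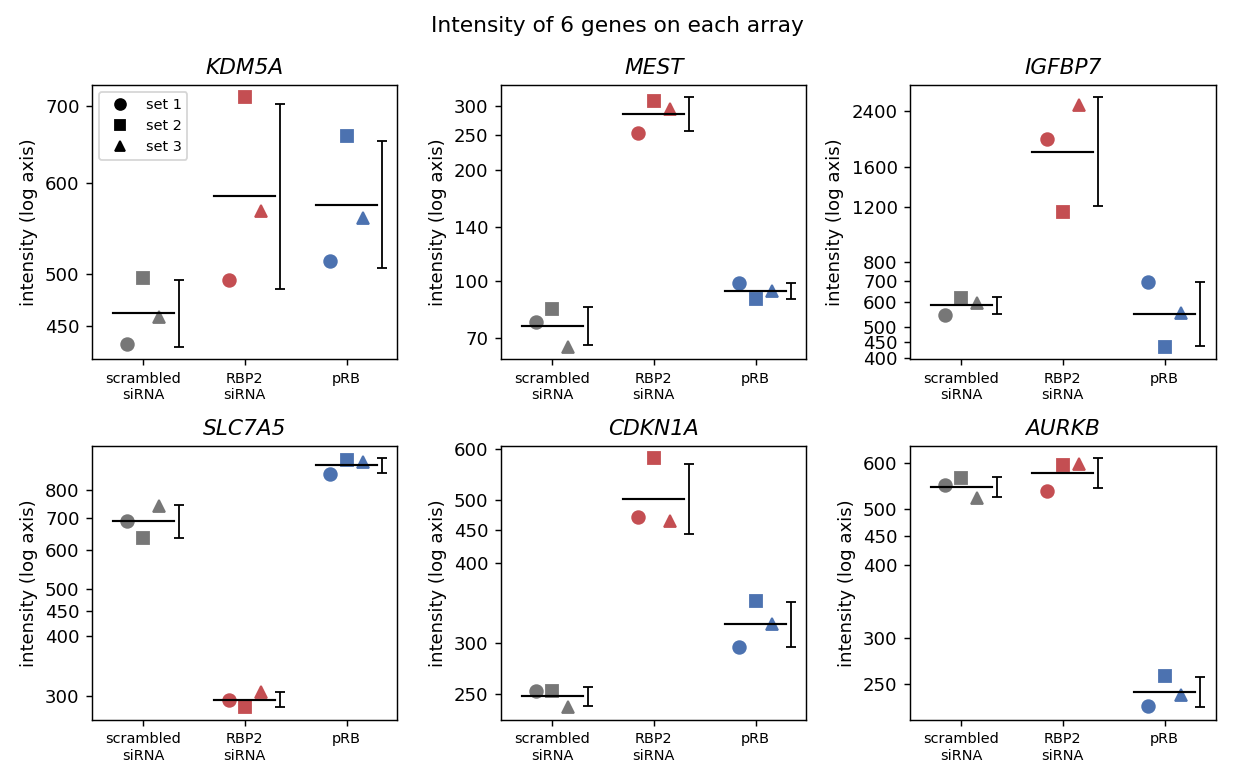
Array intensity (log axes, arbitrary units, axes not starting at 0) of 6 genes in the 3 groups, with 1 symbol per array by numbered set, a horizontal line at the mean of the log2 values and an error bar of 1 SD (n = 3). KDM5A was no lower in RBP2 siRNA arrays (590) than in scrambled siRNA arrays (463), SLC7A5 fell from 690 to 295 in RBP2 siRNA arrays, and AURKB fell from 546 to 242 in pRB arrays.

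The comparison of RBP2 siRNA with scrambled siRNA asks which transcripts change when RBP2 is depleted in cells without functional pRB. In the arrays labelled RBP2 siRNA, MEST, an imprinted gene expressed in mesoderm, rose 3.78-fold, from 75.7 ± 8.80 to 286 ± 29.4 (SD, n = 3 each). IGFBP7, a secreted protein that binds insulin-like growth factors, rose 3.05-fold, from 586 ± 35.8 to 1876 ± 682. SLC7A5, which imports large neutral amino acids, fell 2.34-fold, from 690 ± 52.8 to 295 ± 10.5. By camera the lists of unfolded protein and amino acid stress response and of proteasome genes were lower and that of extracellular matrix genes higher, with 6 of 28, 8 of 30 and 6 of 34 members passing. None of these 3 lists kept its call with an estimated correlation (adjusted p = 0.16, 0.16 and 0.328). Of 13329 probe sets tested, 440 passed in limma at an adjusted p under 0.05, 333 of them higher (249 genes) and 107 lower (85 genes), and 70 of them changed at least 2-fold.

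Among the largest rises in RBP2 siRNA arrays, NPTXR, a neuronal pentraxin receptor, went from 97.5 ± 19.9 to 335 ± 33.7 (log2 change 1.79, adjusted p = 0.0021). HTRA1, a secreted serine protease, was at the floor on all 3 scrambled siRNA arrays and read 182 ± 64.6, at least 3.42-fold higher. Adrenomedullin (ADM), a vasodilator peptide induced by hypoxia, rose from 302 ± 13.3 to 827 ± 116 (log2 change 1.44, SE 0.114, adjusted p = 0.000833). The integrin subunit ITGB4 rose by a log2 change of 1.66. Further rises were of the efflux transporter ABCC3 by 1.65 with 1 scrambled siRNA array at the floor, of TMEM158, a membrane protein induced by Ras, by 1.62, of the matrix protein MATN2 by 1.47 and of apolipoprotein E (APOE) by 1.38. Among the largest falls, CHAC1, which degrades glutathione, went from 322 ± 121 to 91.8 ± 29.4 (log2 change -1.78, SE 0.334, adjusted p = 0.0225). The tetraspanin CD9 went from 514 ± 30.3 to 195 ± 43.5. Basigin (BSG), a chaperone of lactate transporters, went from 732 ± 69.1 to 289 ± 78.2, and cyclin G1 (CCNG1), a p53 target, from 1514 ± 110 to 710 ± 167. The integrin subunit ITGA4 had a log2 change of -1.25, the deoxycytidylate deaminase DCTD of -1.21 and the zinc finger gene ZXDB of -1.50 with 2 RBP2 siRNA arrays at the floor.

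Of 28 measured genes of the unfolded protein and amino acid stress response, 6 fell in RBP2 siRNA arrays and none rose (11 fell adjusted over the list alone). Besides SLC7A5 and CHAC1 they included asparagine synthetase (ASNS, log2 change -1.19), the pseudokinase TRIB3 (-1.12) and the cystine transporter SLC7A11 (-0.69). The list was shifted down by camera with an adjusted p = 2.07e-06, and an adjusted p = 0.16 with an estimated correlation. Of 30 proteasome subunit genes, 8 fell and none rose (22 fell adjusted over the list alone), with a median log2 change of -0.36 (camera adjusted p = 3.85e-17, adjusted p = 0.16 with an estimated correlation). PSMB3 fell from 1884 ± 41.6 to 1264 ± 50.5, PSMB2 from 2722 ± 87.9 to 2070 ± 62.5, PSMD3 from 932 ± 46.8 to 610 ± 92.0 and PSMB7 from 1790 ± 72.7 to 1204 ± 195. The median change of the proteasome list was -0.23 in set 1, -0.50 in set 2, where the RBP2 siRNA array had the actin ratio of 5.03, and -0.29 in set 3. Of 22 genes in the list of ribosome biogenesis and MYC-related genes, 3 fell (6 adjusted over the list alone). They were DDX21 (log2 change -0.68), ODC1, which makes polyamines (-0.67), and NOP16 (-0.60, with 1 of its 2 other probe sets of opposite sign). This list had a camera adjusted p = 1.18e-06 and kept its call with an adjusted p = 0.0481 with an estimated correlation, though with the numbered set as a block that value was an adjusted p = 0.151.

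Of 34 genes of the extracellular matrix and TGF-beta response, 6 rose in RBP2 siRNA arrays and none fell (14 rose and 1 fell adjusted over the list alone). Lysyl oxidase (LOX), which crosslinks collagen, rose by a log2 change of 1.27, fibronectin (FN1) by 0.92 with 1 of 4 other probe sets of opposite sign, fibrillin (FBN1) by 0.73 and the activin subunit INHBA by 0.69. The list had a camera adjusted p = 0.000315, and an adjusted p = 0.328 with an estimated correlation, and its median change was 0.41 in set 1, 0.09 in set 2 with its actin ratio of 5.03, and 0.34 in set 3. Of 28 genes of glycolysis and the hypoxia response, 5 rose (9 adjusted over the list alone). These were ADM, the enolase ENO2 (log2 change 0.77), the phosphofructokinase PFKL (0.69), NDRG1 (0.67) and the mitophagy receptor BNIP3 (0.39), the last chosen after its values were seen. Their list had a camera adjusted p = 0.00374, an adjusted p = 0.196 with an estimated correlation, and lost its call without RBP2 siRNA set 3 (adjusted p = 0.0896). Of 13 genes of senescence-associated secretion, 4 rose (5 adjusted over the list alone), IGFBP7, IGFBP3 (0.91), IGFBP5 (0.85) and the urokinase PLAU (1.33). Their list had a camera adjusted p = 0.0311, an adjusted p = 0.196 with an estimated correlation, and lost its call without scrambled siRNA set 2 (adjusted p = 0.0529) or RBP2 siRNA set 3 (adjusted p = 0.10). It was also lost with a filter at the 60th percentile (0.0709) and with the block without the treated arrays of set 2 (0.0872). The median of this list was 0.20 and 0.19 in sets 1 and 3 and 0.53 in set 2, with its actin ratio of 5.03. Over all sets it went from 0.28 to 0.16 with the mean log2 actin and GAPDH ratio as a covariate (camera adjusted p = 0.0275).

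The other 6 shifted lists were lower in RBP2 siRNA arrays with at most 1 member passing in limma without a block. With the numbered set as a block, 9 genes of mitochondrial translation fell and 1 rose, 3 splicing genes fell and 1 rose, and 2 genes of the TCA cycle fell and 1 rose. With it 5 heat shock, 4 cholesterol biosynthesis and 1 cytosolic ribosomal protein genes fell and none rose. The counts that follow are without the block. Of 49 genes of mitochondrial translation none passed, with 13 at an unadjusted p under 0.05 and 3 falling when adjusted over the list alone (camera adjusted p = 1.59e-06, adjusted p = 0.272 with an estimated correlation). MRPS7 had a log2 change of -0.50 (adjusted p = 0.0548, 0.0108 with the block). Of 41 splicing genes 1 fell and none passed over the list alone (camera adjusted p = 3.58e-05, adjusted p = 0.196 with an estimated correlation). This was the small nuclear ribonucleoprotein SNRPF (log2 change -0.38, adjusted p = 0.0465). The splicing list had medians of -0.07, -0.25 and -0.19 in sets 1 to 3, the lowest in the set with the actin ratio of 5.03. Of 15 heat shock genes none passed, with 5 at an unadjusted p under 0.05 and 1 falling over the list alone (camera adjusted p = 2.3e-06, adjusted p = 0.342 with an estimated correlation). The mitochondrial chaperone HSPA9 had a log2 change of -0.43 (adjusted p = 0.0694, 0.0157 with the block). The heat shock list had medians of -0.09, -0.37 and -0.25 in sets 1 to 3, the lowest in the set with the actin ratio of 5.03. Its median went from -0.25 to -0.10 with the RNA ratio covariate (camera adjusted p = 0.000703). Of 20 cholesterol biosynthesis genes none passed, with 8 at an unadjusted p under 0.05 and 3 falling over the list alone (camera adjusted p = 0.00226, adjusted p = 0.328 with an estimated correlation). DHCR7 had a log2 change of -0.60 (adjusted p = 0.0718, 0.00663 with the block). The cholesterol list had medians of -0.05, -0.20 and -0.19 in sets 1 to 3. With the RNA ratio covariate its median went from -0.15 to -0.08 (camera adjusted p = 0.0319). Of 47 cytosolic ribosomal protein genes none passed, with 10 at an unadjusted p under 0.05 and 0 over the list alone (camera adjusted p = 0.000315, adjusted p = 0.664 with an estimated correlation, adjusted p = 0.117 after quantile normalization). Of 16 genes of the TCA cycle none passed, with 6 at an unadjusted p under 0.05 and 0 over the list alone (camera adjusted p = 0.0439, adjusted p = 0.311 with an estimated correlation). The TCA call was lost without scrambled siRNA set 1 (adjusted p = 0.106) or set 2 (0.0540), and without RBP2 siRNA set 2 (0.0583) or set 3 (0.0879). It was also lost after quantile normalization (0.0788) or median scaling (0.0589), without an intensity trend (0.0622), with the RNA ratio covariate (0.115) and without the treated arrays of set 2 (0.0536).

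Cell cycle lists showed no shift in RBP2 siRNA arrays. Without a block, none of 38 genes of DNA replication passed in limma (8 at an unadjusted p under 0.05, 0 adjusted over the list alone, camera adjusted p = 0.547), and none of 42 mitotic genes (6 at an unadjusted p under 0.05, 0 over the list alone, camera adjusted p = 0.328). With the numbered set as a block, 4 replication genes were higher and 4 lower, and 2 mitotic genes were lower and none higher. The medians of these lists were 0.02 and 0.02 while camera placed both below the other genes. CDKN1A, an inhibitor of cyclin-dependent kinases chosen after its values were seen, rose by a log2 change of 1.02 (SE 0.119, adjusted p = 0.00525).

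With the numbered set as a block, 2181 probe sets passed for RBP2 siRNA against scrambled siRNA, 1267 higher and 914 lower, including all 440. Without the treated arrays of set 2 the block gave 298. The share of calls that were higher, 75.7%, was 61.5% of 392 after quantile normalization and 57.3% of 316 after median scaling. Leave-outs of 1 array, for counts and for named genes, were fitted without the block. The count was then 32, 198 and 47 without scrambled siRNA sets 1, 2 and 3. It was 1597 without RBP2 siRNA set 1 (631 higher and 966 lower, the opposite balance), 283 without RBP2 siRNA set 3, 261 without pRB set 1 and 240 without pRB set 3. Of 43 named genes that passed, MEST, NPTXR, ITGB4, ABCC3, TMEM158, MATN2, ADM, CD9, SLC7A5 and ATP2B4 kept their calls whichever array was left out. The other 33 lost theirs without at least 1 array, 32 of them without scrambled siRNA set 1, 11 without scrambled siRNA set 2, 29 without scrambled siRNA set 3, 5 without RBP2 siRNA set 2, 9 without RBP2 siRNA set 3, 5 without pRB set 1, 1 without pRB set 2 and 5 without pRB set 3. Their highest adjusted p was 0.124 for CHAC1, 0.0796 for IGFBP7, 0.0613 for ASNS, 0.0613 for CCNG1 and 0.178 for NOP16.

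The comparison of pRB with scrambled siRNA asks which transcripts change when pRB is restored, with the day of RNA isolation differing as well. Mitotic genes fell in pRB arrays. KIF20A, a kinesin of the cleavage furrow, fell 2.90-fold, from 647 ± 8.85 to 225 ± 34.0 (SD, n = 3 each). Cyclin B1 (CCNB1), the partner of the mitotic kinase CDK1, fell 2.44-fold, from 798 ± 22.4 to 328 ± 34.1, and the mitotic kinase AURKA fell from 756 ± 50.7 to 312 ± 21.2. Interleukin 11 (IL11) rose 2.46-fold, from 600 ± 51.0 to 1483 ± 219. Of 13329 probe sets, 339 passed in limma, 167 higher (129 genes) and 172 lower (141 genes), and 57 changed at least 2-fold.

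Of 42 measured genes of mitosis, 37 fell in pRB arrays and none rose (42 fell adjusted over the list alone), with a median log2 change of -0.91 and set medians from -0.98 to -0.79. The list had a camera adjusted p = 1.4e-65 and kept its call with an adjusted p = 0.0326 with an estimated correlation, though with the numbered set as a block that value was an adjusted p = 0.145. Besides KIF20A, CCNB1 and AURKA, the kinase AURKB fell from 546 ± 21.1 to 242 ± 14.5 (log2 change -1.18, SE 0.096), and the kinetochore genes CENPE and NDC80 had log2 changes of -1.27 and -1.21. Outside this list, the largest falls included the kinetochore gene CENPM (log2 change -1.17). CDKN3, a phosphatase of cyclin-dependent kinases and also outside the list, fell from 873 ± 30.1 to 389 ± 32.9. So was NRGN, a calmodulin-binding protein of neurons, which fell from 191 ± 3.62 to 84.3 ± 28.1. Of 38 genes of DNA replication regulated by E2F, 8 fell and none rose (22 fell adjusted over the list alone), with a median log2 change of -0.39 (camera adjusted p = 3.07e-23, adjusted p = 0.0807 with an estimated correlation). The ribonucleotide reductase subunit RRM2 fell from 1886 ± 71.8 to 824 ± 70.5, thymidylate synthase (TYMS) had a log2 change of -0.68, the primase PRIM1 of -0.83 and the single-strand binding subunit RPA3 of -0.54. Of 41 splicing genes, 5 fell (11 adjusted over the list alone, camera adjusted p = 1.34e-09, adjusted p = 0.0841 with an estimated correlation). They were SNRPA (log2 change -0.57), SNRPG (-0.51), SNRPD1 (-0.44), SNRPF (-0.42) and SRSF3 (-0.29), the last chosen after its values were seen.

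Among the largest rises in pRB arrays, ABCC3 went from 54.5 ± 11.9, with 1 array at the floor, to 191 ± 37.7 (log2 change 1.73, adjusted p = 0.00314). The long noncoding RNA LINC01711 rose by a log2 change of 1.44, MAP3K7CL by 1.28, the vault protein MVP by 1.23 with 1 scrambled siRNA array at the floor, the pseudokinase TRIB1 by 1.22, the metalloprotease ADAM12 by 1.2, the carboxypeptidase CPA4 by 1.14 and the calcium pump ATP2B4 by 1.09. Cyclin D1 (CCND1), the partner of the kinases that phosphorylate pRB, rose from 163 ± 19.1 to 348 ± 28.3. Of 34 genes of the extracellular matrix and TGF-beta response, 5 rose and none fell (14 rose adjusted over the list alone, camera adjusted p = 3.76e-06, adjusted p = 0.250 with an estimated correlation). These were LOX (log2 change 0.93), tenascin (TNC, 0.74), thrombospondin (THBS2, 0.72), SPARC (0.57) and CCN2 (0.81), the last chosen after its values were seen. Of 28 genes of glycolysis and the hypoxia response, 7 rose (11 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.00478, adjusted p = 0.246 with an estimated correlation). They included NDRG1 (log2 change 1.00), ADM (0.55), the prolyl hydroxylase P4HA2 (0.41) and BNIP3 (0.39). Of 20 cholesterol biosynthesis genes, 3 rose (7 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.00272, adjusted p = 0.370 with an estimated correlation). These were SCD (0.80), a desaturase of fatty acids that the list also holds, MSMO1 (0.78) and HMGCS1 (0.38, its other probe set of opposite sign). Of 31 genes of lysosome and autophagy, 3 rose (12 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.000135, adjusted p = 0.138 with an estimated correlation). These were the sulfatase IDS (0.68), prosaposin (PSAP, 0.44) and the autophagy receptor SQSTM1 (0.41).

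Another 3 lists were lower in pRB arrays with at most 1 member passing in limma without a block, and 1 member of each with it. Of 30 proteasome genes none passed, with 4 at an unadjusted p under 0.05 and 2 falling adjusted over the list alone (camera adjusted p = 3.76e-06, adjusted p = 0.370 with an estimated correlation). PSMA3 had a log2 change of -0.41 (adjusted p = 0.116, 0.0489 with the block). Of 49 genes of mitochondrial translation none passed, with 5 at an unadjusted p under 0.05 and 0 over the list alone (camera adjusted p = 0.000595, adjusted p = 0.426 with an estimated correlation). MRPS34 had a log2 change of -0.46 (adjusted p = 0.064, 0.0379 with the block). Of 15 heat shock genes, 1 fell (1 over the list alone), the mitochondrial chaperonin HSPD1 (log2 change -0.36). That list had a camera adjusted p = 0.0105, an adjusted p = 0.682 with an estimated correlation, and lost its call without pRB set 2 (adjusted p = 0.0975), whose actin ratio was 1.70, or scrambled siRNA set 3 (adjusted p = 0.0622).

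With the numbered set as a block, 894 probe sets passed for pRB against scrambled siRNA, 529 higher and 365 lower, including all 339. Without the treated arrays of set 2 the block gave 333. The share of calls that were higher, 49.3%, was 36.4% of 294 after quantile normalization and 31% of 255 after median scaling. Leave-outs of 1 array were again fitted without the block. The count was 63 without scrambled siRNA set 1, 123 without scrambled siRNA set 2, 76 without scrambled siRNA set 3, 84 without pRB set 1, 209 without pRB set 2, 101 without pRB set 3 and 635 without RBP2 siRNA set 2. Of 42 named genes that passed, ABCC3, LINC01711, IL11, ATP2B4, NDRG1, SCD, KIF20A, CCNB1, AURKA, AURKB, RRM2, CDKN3, TYMS and PRIM1 kept their calls whichever array was left out. The other 28 lost theirs without scrambled siRNA set 1, and 19, 25, 27, 13, 24 and 3 of them without scrambled siRNA set 2, scrambled siRNA set 3, pRB set 1, pRB set 2, pRB set 3 and RBP2 siRNA set 3. Their highest adjusted p was 0.0751 for CCND1, 0.0705 for NDC80 and 0.231 for HMGCS1.

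**Figure D3:**
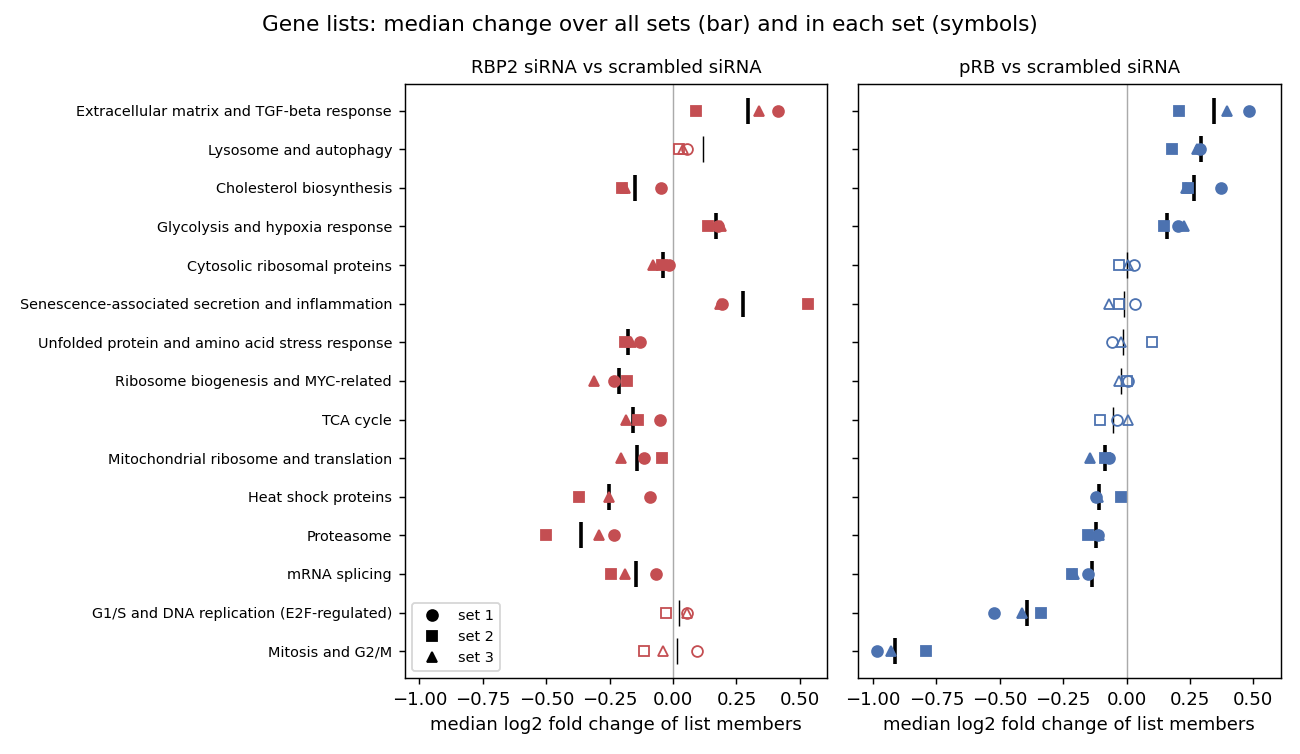
Median log2 fold change of the measured members of each gene list shifted in at least 1 of the comparisons with scrambled siRNA (left, RBP2 siRNA, right, pRB), with bars for the median of the changes fitted over all sets and symbols for the median within each numbered set, filled where camera with its preset correlation gave an adjusted p under 0.05. The mitotic list lay at -0.91 with pRB and 0.02 with RBP2 siRNA, and the proteasome list at -0.12 and -0.36.

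The direct comparison of RBP2 siRNA with pRB asks where the 2 treatments differ, and here plasmid, siRNA and day all differ. Mitotic genes were higher in RBP2 siRNA arrays, with KIF20A at 655 ± 62.4 against 225 ± 34.0 in pRB arrays, 2.93-fold (SD, n = 3 each). Pleiotrophin (PTN), a secreted growth factor, was 2034 ± 223 against 684 ± 57.8 (log2 difference 1.57, SE 0.105, adjusted p = 0.000204). SLC7A5 was lower in RBP2 siRNA arrays, 295 ± 10.5 against 899 ± 30.9 (log2 difference -1.61, SE 0.091, adjusted p = 0.000121), as was heme oxygenase (HMOX1), an oxidative stress enzyme, at 256 ± 10 against 831 ± 86.7. Of 13329 probe sets, 863 passed in limma, 495 higher (395 genes) and 368 lower (297 genes) in RBP2 siRNA arrays, and 130 differed at least 2-fold.

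Among the genes most above pRB in RBP2 siRNA arrays were IGFBP7 (log2 difference 1.70), MEST (1.6), cyclin F (CCNF, 1.46), the nicotinamide methyltransferase NNMT (1.45), the neural proteoglycan CSPG5 (1.44), NDC80 (1.42), HCFC1R1 (1.4) and NRGN (1.4). Among those most below were CHAC1 (-1.61), BSG (-1.52), CRIM1, which binds bone morphogenetic proteins (-1.43), the small heat shock protein HSPB8 (-1.34), SCYL2 (-1.32), EPYC, a cartilage proteoglycan (-1.31, 1 RBP2 siRNA array at the floor), the sialic acid transporter SLC17A5 (-1.31) and TRIB3 (-1.29). Of 42 mitotic genes, 37 were higher in RBP2 siRNA arrays (40 adjusted over the list alone, camera adjusted p = 1.26e-37, adjusted p = 0.134 with an estimated correlation). Of 38 replication genes 14 were higher (20 over the list alone, camera adjusted p = 1.27e-11, adjusted p = 0.165 with an estimated correlation). They included the ligase LIG1 (log2 difference 0.82), PRIM1 (0.71) and TYMS (0.70). Of 28 genes of the unfolded protein and amino acid stress response, 7 were lower (10 over the list alone, camera adjusted p = 0.000587, adjusted p = 0.170 with an estimated correlation). Among them were SLC7A11 (-0.82) and the stress factor ATF3 (-1.16).

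Of 20 cholesterol biosynthesis genes, 8 were lower in RBP2 siRNA than in pRB arrays and none higher (12 lower and 1 higher adjusted over the list alone, camera adjusted p = 3.46e-06, adjusted p = 0.165 with an estimated correlation). They included the fatty acid desaturase SCD (log2 difference -1.01), DHCR7, which completes cholesterol synthesis (-0.99), MSMO1 (-0.68) and HMGCS1 (-0.53). Of 31 genes of lysosome and autophagy, 5 were lower and 1 higher (10 lower and 1 higher over the list alone, camera adjusted p = 0.00154, adjusted p = 0.165 with an estimated correlation). GABARAPL1 lay at -0.86, the protease CTSD at -0.79, SQSTM1 at -0.52 and the glucuronidase GUSB at 0.55. Of 30 proteasome genes, 4 were lower (15 over the list alone, camera adjusted p = 1.12e-05, adjusted p = 0.369 with an estimated correlation). These were PSMD3 (-0.51), PSMB7 (-0.44), PSMC4 (-0.43) and PSMB3 (-0.30). The proteasome list had a median of -0.39 in set 2, with actin ratios of 5.03 and 1.70, and of -0.10 and -0.18 in sets 1 and 3. Over all sets it went from -0.25 to -0.15 with the RNA ratio covariate (camera adjusted p = 0.000187). Of 22 ribosome biogenesis and MYC-related genes, 4 were lower (6 over the list alone, camera adjusted p = 0.00301, adjusted p = 0.165 with an estimated correlation). These were DDX21 (-0.65), NOP16 (-0.65), ODC1 (-0.57) and NOP2 (-0.40). Of 13 genes of senescence-associated secretion, IGFBP7, IGFBP5 (1.2) and IGFBP3 (0.90) were higher and the chromatin protein HMGA2 (-0.69) lower (5 and 1 over the list alone, camera adjusted p = 0.0389, adjusted p = 0.165 with an estimated correlation). The median of the secretion list was 0.34, 0.24 without set 2 and 0.15 with the RNA ratio covariate (camera adjusted p = 0.0232). The secretion call was lost without pRB set 2 (adjusted p = 0.0755) or RBP2 siRNA set 3 (adjusted p = 0.145), and with no filter (0.0804), a filter at the 60th percentile (0.0664) or array weights (0.0693). Of 19 interferon response genes, IFIT1 was higher (1.02, 4 higher over the list alone, camera adjusted p = 0.0388, adjusted p = 0.165 with an estimated correlation). The interferon call was lost without RBP2 siRNA set 3 (adjusted p = 0.281) and after quantile normalization (adjusted p = 0.0530). Of 47 cytosolic ribosomal protein genes, RPS23 was lower (-0.27, 0 over the list alone, camera adjusted p = 0.0302, adjusted p = 0.801 with an estimated correlation). The ribosomal call was lost without pRB set 1 (adjusted p = 0.181) or RBP2 siRNA set 3 (adjusted p = 0.282), and with a filter at the 60th percentile (0.0565) or no intensity trend (0.0922).

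With the numbered set as a block, 2257 probe sets passed for RBP2 siRNA against pRB, 1090 higher and 1167 lower, including all 863. Without the treated arrays of set 2 the block gave 957. Without the block the count was 520 without scrambled siRNA set 1, 1531 without RBP2 siRNA set 1 (575 higher and 956 lower, the opposite balance), 265 without pRB set 1 and 305 without pRB set 3. Of 50 named genes that passed, 31 kept their calls whichever array was left out, among them IGFBP7, MEST, PTN, KIF20A, HMOX1, SLC7A5, BSG, HSPB8 and SCD. The other 19 lost theirs without pRB set 1, 16 without pRB set 3, 7 without pRB set 2, 11 without each scrambled siRNA array, 1 without RBP2 siRNA set 1, 6 without RBP2 siRNA set 2 and 8 without RBP2 siRNA set 3, with a highest adjusted p of 0.0940 for CHAC1 and 0.173 for SCYL2.

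RBP2 siRNA and pRB were then compared for the genes they share, each against scrambled siRNA. In both, 64 probe sets passed and were higher, against 4.17 expected from the separate counts, 1 was lower in both against 1.38, and 5 moved in opposite directions against 5.64. The shared rises with the largest smaller change were ABCC3 (log2 changes 1.65 and 1.73), MVP (1.28 and 1.23), TRIB1 (1.22 and 1.22), LINC01711 (1.21 and 1.44) and ATP2B4 (1.17 and 1.09), and the shared fall was SNRPF (-0.38 and -0.42). These comparisons use the same 3 scrambled siRNA arrays, too few to divide into separate controls of 2 arrays each. The expected counts take the comparisons as independent, whereas controls in common push changes the same way in both. So 4.17 is too low a mark for the 64, and how far they exceed the effect of shared controls was not tested. Across the tested probe sets, which are not independent replicates, the fold changes had Pearson's r = 0.414, while unchanged groups sharing 3 controls gave 0.500 on average (0.473 to 0.536) in 100 simulations. Their covariance was 0.0370 against 0.0198 simulated. Those simulations drew the arrays independently, whereas deviations from the group means were correlated within the sets (0.549, 0.772 and 0.573 between RBP2 siRNA and pRB). With these correlations simulated as well, r was 0.688 and the covariance 0.0159 on average. The shared calls in 1 direction numbered 256 with the numbered set as a block, 30 after median scaling, 5, 25 and 6 without scrambled siRNA sets 1, 2 and 3, 117 without RBP2 siRNA set 1, and 16, 31 and 17 without pRB sets 1, 2 and 3.

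**Figure D4:**
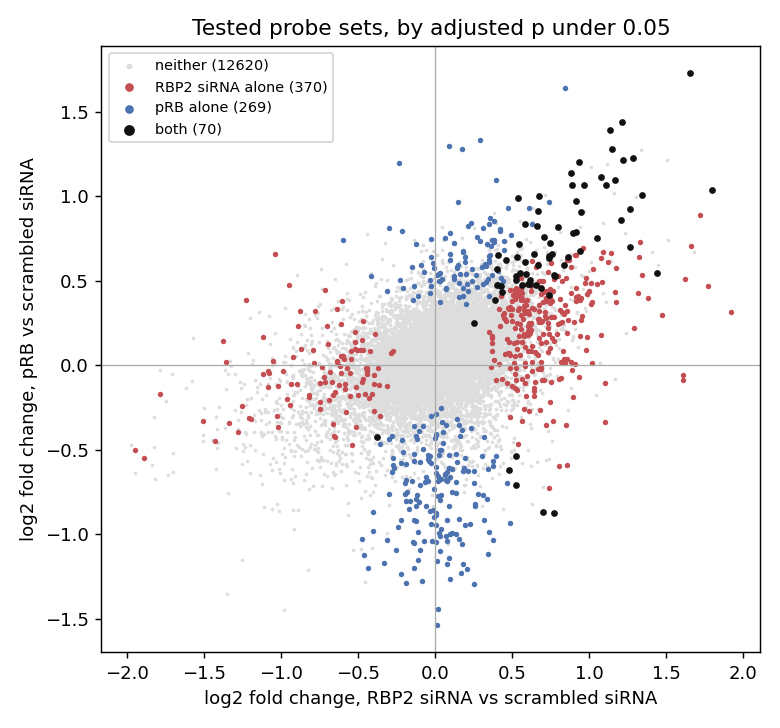
Log2 fold change against scrambled siRNA of each of 13329 tested probe sets with RBP2 siRNA (horizontal axis) and pRB (vertical axis), coloured by whether the adjusted p was under 0.05 in neither comparison (12620), RBP2 siRNA alone (370), pRB alone (269) or both (70). Of the 70, 64 lie in the upper right part.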

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

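Apart from the block by numbered set, the tests in this part were chosen only after the results they bear on were seen. The comparisons of the report do not use the control probe sets of the arrays, and some of their values lay above every scrambled siRNA array by more than 1.4-fold. The ratio of 3' to 5' signal was 5.03 for actin and 2.18 for GAPDH in RBP2 siRNA set 2, and 1.70 for actin in pRB set 2, where the scrambled siRNA arrays reached 1.18 for actin and 1.04 for GAPDH. The probe set for the 3' part of 18S rRNA read 3017 in RBP2 siRNA set 1, where the scrambled siRNA arrays read up to 286, and that for its 5' part read 236 there against up to 137.

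KDM5A was not lower in the arrays labelled RBP2 siRNA (590 against 463, log2 difference 0.34, SE 0.147). Degraded RNA in set 2 could have raised a probe set near the 3' end. Without set 2 the difference was 0.245 (SE 0.119) and still above 0, which argues, on few arrays, against set 2 as the whole cause. A smaller loss of RNA integrity in the other sets stays open. RBP2 siRNA set 3, which is kept when set 2 is left out, also lay above every scrambled siRNA array (actin 1.21, GAPDH 1.14). An exchange of the RBP2 siRNA and scrambled siRNA labels as whole groups stays open, since the adjusted p was 0.226 with all arrays and 0.0363 with the numbered set as a block, chosen beforehand. The pRB arrays, which received the scrambled siRNA, read 577, nearer to the arrays labelled RBP2 siRNA, but of the 440 changed probe sets they lay nearer to those labelled scrambled siRNA for 182 of 333 rises and 99 of 107 falls, and pRB or the day of RNA isolation could move these values too. An siRNA effect on protein alone, and one that had passed by day 5, were not tested.

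Proteasome subunit genes were lower in RBP2 siRNA arrays (median log2 change -0.36), most in set 2. Degraded RNA in set 2 could account for part of the size at most, because without set 2 the median was -0.25 and the SD between the medians of sets 1 and 3 was 0.0407. Loss of 5' signal as measured by the actin and GAPDH ratios may have added to it. With the mean log2 ratio as a covariate the median was -0.27 and the camera adjusted p was 9.78e-18. RBP2 siRNA set 2 lies far above the other arrays in this ratio, so the covariate is hardly a separate test from leaving it out. Without the treated arrays of set 2 the median was -0.28. These camera values are at the preset correlation, and with an estimated correlation the list was not called (adjusted p = 0.16 with all arrays, 0.299 with the block). An effect of the RBP2 siRNA stays open as a hypothesis, and with it the label exchange above, which would reverse the direction, and an off-target effect of the siRNA, which was not tested.

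Mitotic genes were lower in pRB arrays (median log2 change -0.91). Without set 2 the median was -0.97 and the SD between the medians of sets 1 and 3 was 0.0386, which argues against degraded RNA in set 2 as its cause. The day of RNA isolation cannot be told apart from pRB, since all day 3 arrays carry pRB and the change of -0.91 belongs to both. Restored pRB, a repressor of E2F-regulated genes, is a candidate explanation that the design names and that stays untested apart from the day.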

How the results depend on the processing

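In order RBP2 siRNA against scrambled siRNA, pRB against scrambled siRNA and RBP2 siRNA against pRB, 440, 339 and 863 probe sets passed, and 65 passed in 1 direction in both comparisons with scrambled siRNA. The block by numbered set gave 2181, 894 and 2257, with 256 shared, but without the treated arrays of set 2 it gave 298, 333 and 957, with 50 shared. An adjusted p under 0.10 gave 883, 684 and 1581, with 144 shared. Fitting only the 6 arrays compared gave 108, 905 and 230, with 39 shared. A fold change of at least 1.5 left 219 for pRB, 521 for RBP2 siRNA against pRB and 37 shared. Array weights gave 2253 for pRB and 185 shared, median scaling 30 shared and no intensity trend 40 shared. Of the settings added after the RNA ratios were seen, leaving out the treated arrays of set 2 gave 603 for pRB, and the ratio covariate gave 988 for pRB, 1387 for RBP2 siRNA against pRB and 135 shared. The causes of these differences were not tested, except that a threshold moves the count by construction. The RBP2 siRNA set 2 array enters neither group mean of pRB against scrambled siRNA. Leaving it out gave 635 there, against 339, a change that can come only through the estimate of spread shared by the arrays. Leaving out 1 array or 1 whole set, without the block, gave 0 to 1597, 0 to 635 and 0 to 1531, with 0 to 117 shared. Limma counts of 0 came from leaving out set 1 or set 3. Without set 2 as many arrays remain, so their number alone does not account for the counts of 0. Without set 1, 0 passed against scrambled siRNA for RBP2 siRNA (2466 at an unadjusted p under 0.05) and for pRB (982), and 5 for RBP2 siRNA against pRB. Without set 3, 0 passed in any comparison (1816, 1326 and 1913 unadjusted). Without set 2 the counts were 147, 213 and 584.

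Shifted lists numbered 12, 10 and 10. An estimated correlation left 1, 1 and 0 in camera. Fry, which does not compare a list with other genes, called 6, 8 and 10 lists, of which 6, 7 and 9 were among the shifted ones. With RBP2 siRNA against scrambled siRNA it called 6 of the 12, among them proteasome genes (fry adjusted p = 0.00612). The others, such as heat shock (0.136) and cholesterol genes (0.14), were not called. Leaving out arrays or sets gave 9 to 12, 9 to 11 and 7 to 12. Robust moderation was not run for lists, as camera has no such setting, nor was 1 probe set per gene, which lists already use. Of the genes named, those that turned direction were KDM5A and RB1, in comparisons where neither passed, and the cause was not tested. Medians of some lists that were not shifted turned as well. Without the treated arrays of set 2, osteoblast genes with RBP2 siRNA went from -0.080 to 0.060 and p53 targets with pRB from 0.059 to -0.030. The dimmer KDM5A probe set for pRB went to -0.017 with quantile normalization, -0.0019 with median scaling and -0.030 without the treated arrays of set 2. Its leave-outs ran from -0.15 to 0.196. For RBP2 siRNA it went to 0.19 with array weights, 0.094 with the block without the treated arrays of set 2, and leave-outs ran from -0.193 to 0.101. Against pRB it went to 0.0078 without those arrays, with or without the block, and leave-outs ran from -0.175 to 0.0149. The brighter KDM5A probe set for RBP2 siRNA against pRB went to -0.019 without those arrays, with or without the block, to -0.12 with the covariate, and leave-outs ran from -0.119 to 0.145. RB1 for pRB went to 0.032 without those arrays, and leave-outs ran from -0.375 to 0.032. Values near the floor limit folds, which are then lower bounds.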

Other observations

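The splits of the arrays and the test of ATF4 targets were chosen before their results were seen, and the tests on imprinted and testis genes after. In lists that were not shifted in the comparison concerned, some genes moved singly. In pRB arrays the linker histone H1-2 rose (log2 change 0.73, adjusted p = 0.0395), and the variant H2AZ1 (-0.44) and H1-10 (-0.55) fell, among 11 histone genes (camera adjusted p = 0.737, median 0.18). Lamin B1 (LMNB1), of the nuclear lamina, fell (-1.09, adjusted p = 0.0494), the chromatin protein HMGA2 rose (0.75, adjusted p = 0.0189) and the nucleolar protein fibrillarin (FBL) fell (-0.44, adjusted p = 0.0127). LMNB1 and HMGA2 are in the list of senescence-associated secretion (camera adjusted p = 0.823 with pRB) and FBL in that of ribosome biogenesis (camera adjusted p = 0.236). Of 15 osteoblast genes, SPARC and the cadherin CDH11 (0.65) rose in RBP2 siRNA arrays (camera adjusted p = 0.650), and SPARC and BAMBI (0.51), an inhibitor of TGF-beta signalling, rose in pRB arrays (camera adjusted p = 0.663). In RBP2 siRNA arrays the muscle regulator MYOD1 rose (1.00, adjusted p = 0.00999), as did the cartilage regulator SOX9 (1.09, adjusted p = 0.0372) and the ubiquitin-like ISG15 (0.51, adjusted p = 0.0490). Their lists were not shifted (camera adjusted p = 0.814 for 6 muscle genes, 0.814 for 7 chondrocyte genes and 0.547 for 19 interferon genes). These genes were chosen after their values were seen.

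Other lists showed no shift with RBP2 siRNA or with pRB against scrambled siRNA. The camera adjusted p was 0.547 and 0.128 for 54 genes of oxidative phosphorylation, 0.993 and 0.335 for 12 enzymes of histone H3K4 methylation, which include KDM5A, 0.547 and 0.823 for 13 HOX genes, 0.547 and 0.823 for 16 p53 targets, and 0.993 and 0.823 for 7 CDK inhibitors and pocket proteins. For markers of other cell types it was 0.814 and 0.874 for 5 epithelial genes, 0.757 and 0.874 for 6 blood genes, 0.547 and 0.823 for 5 adipocyte genes, and 0.864 and 0.823 for 10 neuronal genes, of which the enolase ENO2 rose in both. With pRB, oxidative phosphorylation was lower after median scaling (adjusted p = 0.0331), without pRB set 1 (0.0468) or without scrambled siRNA set 3 (0.0304), and cytosolic ribosomal proteins without scrambled siRNA set 3 (0.0395 against 0.403). Between RBP2 siRNA and pRB, heat shock genes were lower with the block (adjusted p = 0.0344 against 0.0886, but 0.735 with the block and an estimated correlation) and without RBP2 siRNA set 1 (0.0115), RBP2 siRNA set 3 (0.0467) or pRB set 2 (0.0491). Their set medians were -0.04, -0.37 and -0.14, the lowest in the set with the highest actin ratios, and the adjusted p was 0.377 without the treated arrays of set 2 and 0.652 with the ratio covariate. Without RBP2 siRNA set 2, splicing genes were higher (0.0213 against 0.233) and mitochondrial translation genes lower (0.0319 against 0.187). Without the treated arrays of set 2, chondrocyte genes were higher (0.0365 against 0.394). In fry the H3K4 enzymes were higher with pRB (adjusted p = 0.00383, 0.0133 with the block). In RBP2 siRNA against pRB arrays fry placed them lower (0.0155), but not with the block (0.168), and their median was 0.02 with 7 of 12 above 0. Mean and camera differed in sign for several lists that were not shifted. With RBP2 siRNA, camera placed oxidative phosphorylation (mean 0.006) and lysosomal genes (mean 0.023, median 0.12, adjusted p = 0.993) below other genes. It did so too for replication genes (mean 0.0095), H3K4 enzymes (0.065), blood markers (0.063) and core histones (0.018). With pRB the same held for cytosolic ribosomal proteins (mean 0.0013), stress response (0.0056), senescence-associated secretion (0.011) and core histone genes (0.020).

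The 6 arrays of each comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05, and in each case 1 split, the real one, gave a count as large. The real counts of probe sets were 440, 339 and 863 and the highest of the other splits 0, 0 and 476, in the order used above. For lists they were 12, 10 and 10 against 9, 9 and 8. Of the splits that, like the real one, put arrays of each set on different sides, the highest gave 0 probe sets in each comparison and 6, 8 and 6 lists. The split with 476 set RBP2 siRNA set 1, pRB set 1 and pRB set 3 against the other treated arrays, which are the 3 with the highest actin and GAPDH ratios of the 6, a structure of the samples that follows RNA integrity.

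A hypothesis for the fall of genes of the unfolded protein and amino acid stress response in RBP2 siRNA arrays is lower transcription by ATF4, the factor that induces many of them. It was tested on genes outside the list. The 12 measured genes known to be induced by ATF4, tRNA synthetases and the tRNA exporter XPOT, had a median log2 change of -0.28, with 11 of 12 below 0 and 1, XPOT, passing in limma (camera p = 1.3e-06, p = 0.00908 with an estimated correlation). The 5 other cytosolic synthetases, 1 of which passed, had a median of -0.14 (camera p = 0.0330, p = 0.0725 with an estimated correlation). The exact permutation test over genes of the difference, two-sided, gave p = 0.510. The lower synthetases are in line with this hypothesis, but the test does not separate it from a change of all synthetases.

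MEST is imprinted, and the other 14 measured imprinted genes were tested as a list written after the fold changes were seen. Their median log2 change in RBP2 siRNA arrays was 0.0748 (SD over genes 0.262) against 1.92 for MEST. None of the 14 passed in limma (camera adjusted p = 0.511 over 6 such tests), so no shift shared by these genes was found. MEST was picked for its large rise, so its distance from their median does not test a shared cause. A list of testis genes written after the fold changes were seen had 10 measured members in RBP2 siRNA arrays, 9 of them below 0 with a median of -0.20. None passed in limma (camera p = 0.00161, adjusted over 6 such tests 0.00966, p = 0.0691 with an estimated correlation).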
